A study of Homo sapiens with 21 samples.

How the data were processed

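Monocytes were sorted by flow cytometry from blood mononuclear cells of 4 healthy donors into classical (CD14++CD16-), intermediate (CD14++CD16+) and non-classical (CD14+CD16++) subsets, and the intermediate subset was also sorted from 5 patients with autoimmune uveitis. Per the labels' protocols, total RNA was purified on columns and biotin-labelled cRNA was hybridised to Affymetrix whole-genome expression arrays, which carry 1 sample each in a single colour. The 17 arrays gave 21 records, because the 4 healthy intermediate arrays were processed in 2 sets: once with the classical and non-classical arrays (12 arrays) and once with the patient arrays (9 arrays). Healthy-donor numbers name the same person in the 3 subsets. Patient numbers name other people.

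The authors deposited a single table of processed values for both sets, and the submitters' processing notes name RMA, a method that corrects background, normalizes between arrays and summarises the probes of each probe set, and limma 3.23.6. The version of RMA, the background and normalization settings and the treatment of the patients are not given in the sources used here. The deposited values are intensities on a linear scale, inferred from their range and from whole numbers filling all of the 12-array set, and they are not centred per gene. Because the test had been planned for log2 values, the log2 of each deposited intensity was taken before any test, with no pseudocount. Median intensities per array were, for donors 1 to 4, 61, 63, 63 and 62 (classical), 63, 63, 61 and 60 (intermediate) and 62, 62, 68 and 65 (non-classical). In the second set they were 59.1, 59.3, 56.9 and 56.3 for the healthy intermediate arrays and 61.7, 57.2, 56.7, 57.6 and 54.4 for patients 1 to 5. No scanner files or detection calls were used here, so a dim probe set carries no statement on detection, and the number of arrays limits the precision. The 2 sets were normalized separately, so every test stayed within a set.

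The table held 54675 probe sets. The annotation table gave 1 gene to 41097 of them, several genes to 1801 and none to 11777, and 41043 probe sets matched a reference entry by Entrez number, with 0 symbols changed. The 62 control probe sets were left out of the tests, as were probe sets with several genes or none. Each of the 19775 genes was read through its probe set with the highest mean. A gene was tested where at least 4 arrays of the set reached the median of all values of that set, an intensity of 63 in the 12-array set and 57.7 in the 9-array set, which left 13151 and 12867 genes. FCGR3A (CD16) has no probe set of its own in this annotation. CD16 was therefore read through a probe set assigned to FCGR3B, a near-identical paralog, and its level is uncertain between the 2 genes. Metallothionein probe sets can also cross-hybridise. Probe sets of 1 gene differed in sign for HLA-DOA and CD74 between intermediate and non-classical monocytes and for FKBP5 and HBB between patients and healthy donors.

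Group means were fitted with limma 3.58.1 (lmFit, contrasts, eBayes with its default prior) in R 4.3.3 with the package data.table (version 1.17.8), and figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Tests were two-sided, Benjamini-Hochberg adjusted over all genes of a contrast, and called at an adjusted p under 0.05. The 3 subsets shared 1 fit, and the patient set had its own. Differences are on the log2 scale with the standard error (SE) of the fit. Fixed lists of genes, 22 in all, were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 22 lists of a contrast. The lists were classical and non-classical monocyte markers, MHC class II presentation, glucocorticoid response, interferon-stimulated genes, inflammatory cytokines and NF-kB targets, immediate early genes, anti-inflammatory and scavenger genes, pattern recognition receptors, chemotaxis and adhesion receptors, complement components, heat shock and unfolded protein response, ribosomal proteins, proliferation, and markers of T cells, B cells, NK cells, platelets, erythroid cells, neutrophils, conventional dendritic cells and plasmacytoid dendritic cells. List counts are also given adjusted over the list alone. Camera with an estimated correlation, fry and an exact permutation of the list mean per array were alternatives.

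The genes named were set by a rule. CD14, FCGR3A, CCR2, CX3CR1 and HLA-DRA were always named for the subsets (1 further item of the rule is not reported here), with the 8 largest increases and the 8 largest decreases among called genes that moved the same way in 4 of 4 donors. For each list described, 2 to 4 members with the largest differences were added, called members first, while lists given only by their median and adjusted p name no member. For the patients, groups that did not overlap took the place of donors, fewer than 8 passing genes were filled to 8 with the smallest p, and FKBP5, TSC22D3, CD163, CD14, FCGR3A, IL1B, TNF and CXCL8 were always named. Sex-linked genes, HLA-DRB and HLA-DQ chains, genes with common deletions and receptor segments were never named. Lists, tests, rule and most alternatives were fixed before the data were examined. The metallothionein, GIMAP and eosinophil granule families, RNASE2, PRG2 and SLAMF7 were chosen after their values were seen.

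RNA quality was read from the ACTB and GAPDH control probe sets as the log2 level of the 3' probe set minus that of the 5' probe set, which grows as RNA is degraded. This difference is an indirect sign, and its cause in single arrays was not tested. The arrays called most degraded are those where it was largest. Alternatives were no filter or a stricter filter on dim genes (quantile 0.75 in place of 0.5), the mean of all probe sets of a gene, every probe set on its own, a repeated quantile normalization, centring of each array, an intensity trend with a robust prior, array weights, a minimum 2-fold difference, the donor as a fixed or random block, a fit of only the 2 subsets compared, and leaving out each array in turn. Added after seeing the data were fits without the most degraded arrays, with the 3' minus 5' difference as a covariate, without the 2 non-classical arrays highest in NK markers, the donor block combined with other choices, the exact test of list means, and the named genes under alternatives planned only for counts. The pairing comes from the labels, which give the same donors for the 3 subsets. Deviations from the group means correlated between the intermediate and classical arrays of a donor at 0.505 to 0.763, between non-classical and classical arrays at 0.293 to 0.612 and between intermediate and non-classical arrays at -0.123 to 0.427.

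The scripts were tested on simulated data. For the comparison of intermediate with classical monocytes, with 13151 genes and 50 changed at each size, 68% of genes changed by 1 on the log2 scale were recovered and 100% of those changed by 2, 3 or 4, with 13 false among 197 calls. For the patient comparison, with 12867 genes, the shares at changes of 1, 2, 3 and 4 were 50%, 86%, 94% and 98%, with 11 false among 175 calls. A list shifted by 0.5 was called in both simulations, and 0 of the 21 other lists were. The simulated genes varied independently of each other and held no differences between donors. The simulations therefore do not show how often a list is called wrongly where its genes move together. With 197 and 175 calls, the adjusted threshold was also less strict than in the real comparisons, which called 2 genes and 1 gene. The shares recovered therefore do not hold for those comparisons.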

Results

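Blood monocytes were compared as 3 subsets set apart by the surface proteins CD14, a co-receptor for bacterial lipopolysaccharide, and CD16, a receptor for the constant part of IgG. Classical, intermediate and non-classical monocytes came from the same 4 healthy donors, and intermediate monocytes also from 5 patients with autoimmune uveitis, an immune-mediated inflammation of the eye. Gene expression was measured on 17 arrays, 12 of the healthy subsets and 5 of patients, with the 4 healthy intermediate arrays processed a second time beside the patients. Median intensities lay between 60 and 68 in the 12-array set and between 54.4 and 61.7 in the 9-array set. The number of arrays, 4 or 5 per group, limits the precision of every value. A group mean under the threshold for dim genes (intensity 63 in the 12-array set and 57.7 in the 9-array set) leaves the size of a difference from it uncertain. This held for FCGR3B, C1QB, C1QC and UICLM in classical arrays, for CLC, SH2D1B, ETS1, VMO1, TYMS, GZMB and CD247 in classical and intermediate arrays, and for CD3E in intermediate arrays. It held for BANK1 in intermediate and non-classical arrays, for THBS1, S1PR3, ALDH1A1, CRISPLD2, CCR2 and SERPING1 in non-classical arrays, for TUBB1, PPBP, CST7 and HBD in healthy arrays of the second set, and for NAP1L5 in patient arrays.

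RNA quality differed between arrays. The ACTB 3' minus 5' difference was 0.04 ± 0.13 (SD, n = 4) in classical, 0.65 ± 0.86 in intermediate, 0.23 ± 0.21 in non-classical and 1.73 ± 2.54 (n = 5) in patient arrays. The mean of ACTB and GAPDH reached 6.19 in patient 1 and 1.65 in the intermediate array of donor 1, and stayed between -0.06 and 0.64 elsewhere. Groups did not separate by exact permutation tests (two-sided, unadjusted p 0.171 to 0.746, adjusted p 0.457 to 0.746 over 8 tests).

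**Figure D1:**
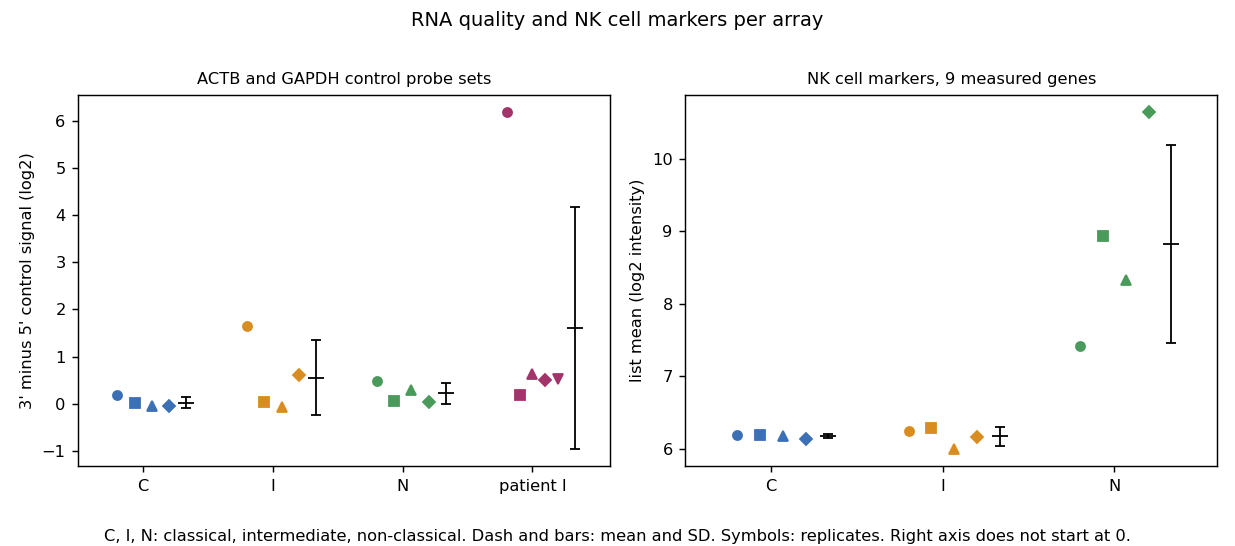
RNA quality as the mean 3' minus 5' log2 difference of the ACTB and GAPDH controls per array, and the mean log2 intensity of the NK cell markers per array; each point is 1 array of the named group, and the dash with bars is the mean and SD. Patient array 1 stands at 6.19, and the non-classical arrays spread from 7.41 to 10.65 in NK cell markers.

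The first comparison asked how intermediate monocytes differ from the classical monocytes of the same donors. FCGR3B, through which CD16 transcripts were read, was higher in intermediate monocytes, at 7.61 ± 0.22 against 5.53 ± 0.27 log2 intensity (SD, n = 4 each). C1QA, a chain of complement C1q, was 3.40-fold higher, at 8.15 ± 0.39 against 6.38 ± 0.15. Both were higher in 4 of 4 donors and carried a limma adjusted p of 0.0406, with log2 differences of 2.08 (SE 0.28) and 1.76 (SE 0.23). They were the only 2 of 13151 genes to pass, while 203 genes (171 higher, 32 lower) had an unadjusted p under 0.05 against 658 expected by chance. This fit left differences between donors in the spread, and with the donor as a fixed block 533 genes (467 higher, 66 lower) had an unadjusted p under 0.05.

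Non-classical monocyte markers shifted upward as a list in intermediate monocytes. All 19 measured members had positive differences with a median of 0.66 (camera adjusted p = 2.91e-20). None passed over all genes, and 5 were higher when adjusted over the list alone. CDKN1C, a cyclin-dependent kinase inhibitor, stood at 9.71 ± 0.94 against 8.11 ± 0.42, a difference of 1.60 (SE 0.38). CSF1R, the receptor for macrophage colony-stimulating factor, differed by 1.07 (SE 0.30), the small GTPase RHOC by 1.05 (SE 0.28) and MTSS1 by 1.05 (SE 0.26). The fractalkine receptor CX3CR1 differed by 0.66 (SE 0.37) and did not pass. Complement components shifted upward too (median 0.24, mean 0.46, adjusted p = 1.21e-05), with 9 of 13 members positive, 1 called and 3 higher adjusted over the list alone. Beside C1QA, the other C1q chains C1QB and C1QC differed by 1.87 (SE 0.52) and 1.87 (SE 0.46) without passing, and the C1 inhibitor SERPING1 by 0.57 (SE 0.23). These 2 lists were the only ones of this comparison whose call held with an estimated correlation (adjusted p = 0.0234 each).

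Inflammatory cytokines and NF-kB targets shifted downward, with 20 of 21 members negative and a median of -0.46 (adjusted p = 8.86e-08). The call was lost at adjusted p = 0.318 with an estimated correlation. IL1A had a difference of -1.29 (SE 0.90), the neutrophil attractant CXCL3 of -1.22 (SE 0.53), the chemokine CCL20 of -1.16 (SE 1.18) and IL6 of -1.11 (SE 0.49). Classical monocyte markers had negative differences in 18 of 18 members with a median of -0.22 (adjusted p = 8.28e-07), a call lost at adjusted p = 0.318 with an estimated correlation. Their largest differences were in the glutathione transferase relative MGST1 (-0.82, SE 0.45), coagulation factor F5 (-0.74, SE 0.37) and the calcium-binding protein S100A12 (-0.59, SE 0.43). CD14 and the chemokine receptor CCR2 differed by -0.19 (SE 0.33) and -0.22 (SE 0.44), each with 2 donors higher and 2 lower. Interferon-stimulated genes (21 of 23 positive, median 0.21) had adjusted p = 0.00268, and adjusted p = 0.674 with an estimated correlation. LY6E and ISG15 differed by 0.85 (SE 0.45) and 0.53 (SE 0.32). MHC class II presentation (9 of 12 positive, median 0.15) had adjusted p = 0.00839, and adjusted p = 0.216 with an estimated correlation. Its members HLA-DOA, HLA-DPB1 and CD74, the invariant chain, differed by 0.52 (SE 0.18), 0.44 (SE 0.20) and 0.41 (SE 0.14), and HLA-DRA by -0.05 (SE 0.18). Chemotaxis and adhesion receptors (12 of 16 positive, median 0.20) had adjusted p = 0.0103, and adjusted p = 0.216 with an estimated correlation. The integrin chain ITGAL and the selectin ligand SELPLG differed by 0.68 (SE 0.26) and 0.45 (SE 0.17). The glucocorticoid response list (14 of 22 negative, median -0.12) had adjusted p = 0.0276, and adjusted p = 0.674 with an estimated correlation. Its members ALOX5AP, which serves leukotriene synthesis, and the kinase PDK4 differed by -0.89 (SE 0.66) and 0.63 (SE 0.78). In these 6 lists 0 genes passed the limma test, over all genes or adjusted over the list alone.

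The donor 1 intermediate array, with the 3' minus 5' difference of 1.65, moved several of these values. Without it 0 genes passed (99 at an unadjusted p under 0.05), with FCGR3B at 2.04 and C1QA at 1.65 and adjusted p = 0.206 for both (ranges over their alternatives 0.00195 to 0.302 and 0.00884 to 0.271). Both calls also ended with no filter on dim genes (adjusted p = 0.0544 each) and with the 3' minus 5' difference as a covariate (0.271 each), and C1QA under a repeated quantile normalization (0.0615). With the covariate FCGR3B differed by 2.10 and C1QA by 1.58. Without the donor 1 intermediate array classical markers had a median of -0.08 (adjusted p = 0.129, range 9.36e-08 to 0.872) and the glucocorticoid list turned to 0.06 (adjusted p = 0.513, range 7.69e-04 to 0.964). With the 3' minus 5' covariate the classical and interferon calls ended too, with medians of -0.03 and 0.12 (adjusted p = 0.477 and 0.423). Leaving out donor 1, 2, 3 or 4 among the classical arrays, donor 3 or 4 among the intermediate arrays or donor 1 among the non-classical arrays also left 0 genes, and without the donor 2 intermediate array 1 gene passed. With the donor as a fixed block 1 gene passed in place of 2: C1QA kept its call (adjusted p = 0.0194) and FCGR3B did not (adjusted p = 0.0564), at an unchanged difference of 2.08. With the donor as a random block both passed (adjusted p = 0.0162 and 0.0170). The blocked fit also ended the glucocorticoid call (adjusted p = 0.0615) and called the immediate early list, which had a median of -0.13 (adjusted p = 0.0553 without and 0.0237 with the block, range 3.62e-05 to 0.964). Its members NR4A2 and NR4A1, nuclear receptors, differed by -0.39 (SE 0.35) and 0.34 (SE 0.26). Other list calls ended without 1 array: interferon without classical donor 3 (adjusted p = 0.274, range 1.96e-06 to 0.964), MHC class II without intermediate donor 2, intermediate donor 3 or classical donor 4 (0.0617, 0.168 and 0.063, range 6.38e-05 to 0.419), chemotaxis without classical donor 2, intermediate donor 3 or intermediate donor 4 (0.0637, 0.131 and 0.179, range 4.10e-04 to 0.681) and the glucocorticoid list without classical donor 3 or 4 (0.235 and 0.218).

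**Figure D2:**
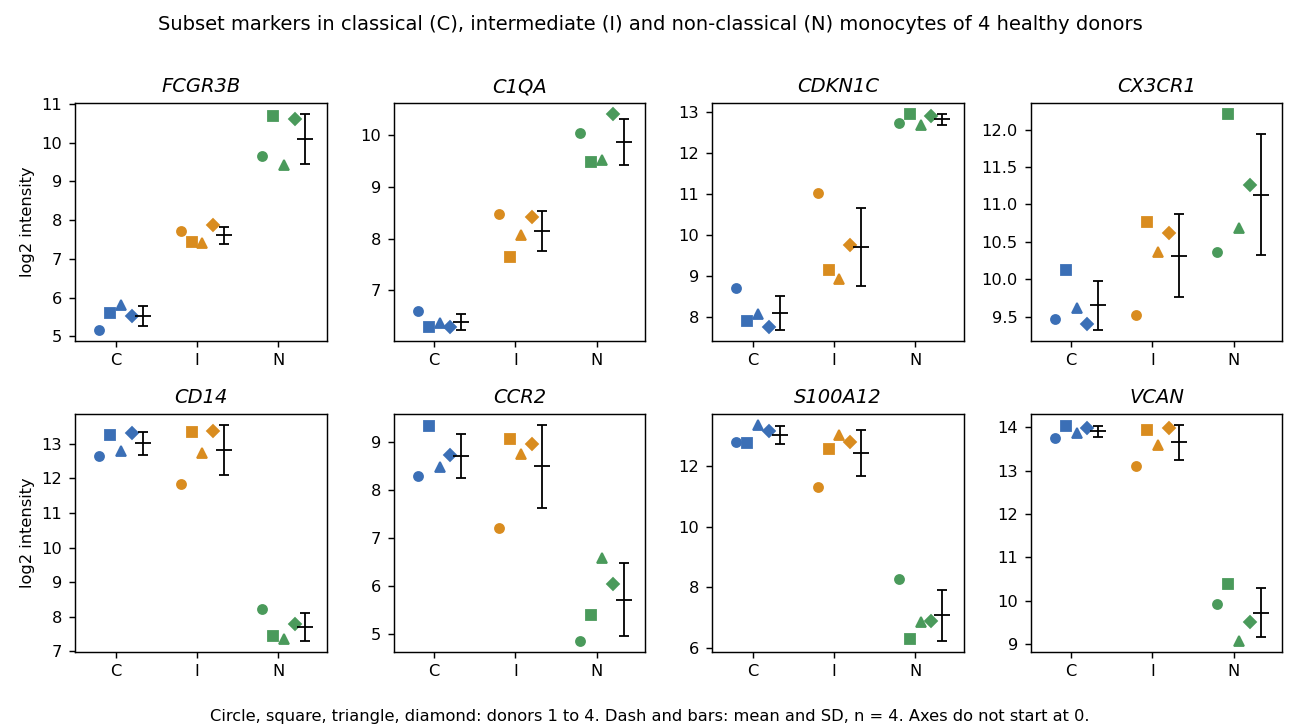
Log2 intensity of 8 genes in classical (C), intermediate (I) and non-classical (N) monocytes; points are the 4 donors and the marks with bars are the mean and SD. FCGR3B rises from 5.53 in classical to 7.61 in intermediate and 10.10 in non-classical arrays, while CD14 lies at 12.83 in intermediate and 7.70 in non-classical arrays.

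The second comparison set intermediate against non-classical monocytes. CD14 was 35.0-fold higher in intermediate monocytes, at 12.83 ± 0.73 against 7.70 ± 0.40 log2 intensity (SD, n = 4 each), a log2 difference of 5.13 (SE 0.33, limma adjusted p = 5.41e-06). THBS1, thrombospondin, stood at 10.86 ± 0.91 against 4.82 ± 0.51 (6.04, SE 0.43, adjusted p = 1.04e-05), where the non-classical level lay under the dim threshold. S100A12 was higher by 5.37 (SE 0.43), the ribonuclease RNASE6 by 4.96 (SE 0.36), the haemoglobin scavenger receptor CD163 by 4.89 (SE 0.36), the sphingosine phosphate receptor S1PR3 by 4.49 (SE 0.41), the retinal dehydrogenase ALDH1A1 by 4.40 (SE 0.41) and the glutaminyl cyclase QPCT by 4.23 (SE 0.41). All 8 were higher in 4 of 4 donors, as the rule for naming them required. In all, 933 genes passed, 732 higher and 201 lower in intermediate monocytes, of which 556 differed at least 2-fold (451 higher, 105 lower).

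Classical monocyte markers accounted for several of these genes: 17 of 18 were called higher, 18 of 18 adjusted over the list alone, and the list median was 2.79 (adjusted p = 4.27e-28, and 0.0252 with an estimated correlation). The matrix proteoglycan VCAN was higher by 3.93 (SE 0.26), the formyl peptide receptor FPR1 by 2.51 (SE 0.28) and CCR2 by 2.77 (SE 0.44). Of 19 non-classical markers 12 were called lower, 17 adjusted over the list alone, with a median of -1.54 (adjusted p = 3.13e-20, and 0.0252 with an estimated correlation). CDKN1C was at 12.82 ± 0.13 in non-classical arrays, a difference of -3.11 (SE 0.38). The creatine kinase CKB differed by -2.96 (SE 0.25), VMO1 by -2.65 (SE 0.41), the transcriptional repressor HES4 by -2.41 (SE 0.31) and FCGR3B by -2.49 (SE 0.28). CX3CR1 differed by -0.81 (SE 0.37, adjusted p = 0.228) and HLA-DRA by 0.32 (SE 0.18, adjusted p = 0.299), and neither passed. The glucocorticoid response list had a median of 0.98 with 9 of 22 members higher, 11 adjusted over the list alone (adjusted p = 7.16e-06). It was lost at adjusted p = 0.263 with an estimated correlation. Among its members were THBS1, CD163, FPR1 and CRISPLD2 (4.01, SE 0.39), of which CD163 and FPR1 are also on the classical list. Anti-inflammatory and scavenger genes had a median of 1.02 with 6 of 11 higher, 7 adjusted over the list alone (adjusted p = 0.00633, and adjusted p = 0.122 with an estimated correlation), among them the scavenger receptor STAB1 at 3.32 (SE 0.32) and the interleukin-1 receptor antagonist IL1RN at 2.87 (SE 0.68). MHC class II presentation did not pass as a list (median 0.32, adjusted p = 0.0521), although 4 of 12 members were higher, over all genes and adjusted over the list alone. The peptide-loading chains HLA-DMB and HLA-DMA were higher by 1.57 (SE 0.17) and 1.53 (SE 0.18). HLA-DOA and CD74 were also called (0.74 and 0.59, adjusted p = 0.0262 and 0.0281). Both calls ended under centring of each array (0.0578 and 0.0920), array weights (0.0667 and 0.0549) and without some single arrays. With the mean of all probe sets HLA-DOA differed by 0.07 (adjusted p = 0.711). Inflammatory genes (median 0.60, adjusted p = 0.0793) had 3 of 21 members higher, 4 adjusted over the list alone, namely CXCL3 at 2.68 (SE 0.53), the related CXCL2 at 2.26 (SE 0.51) and the stress-induced IER3 at 2.13 (SE 0.30). Pattern recognition receptors (median 0.33, adjusted p = 0.0595) had 3 of 16 higher, 4 adjusted over the list alone, including the flagellin receptor TLR5 at 1.18 (SE 0.23) and the lipoprotein receptor TLR2 at 1.05 (SE 0.24). Under a repeated quantile normalization the MHC class II and inflammatory lists passed, at adjusted p = 0.0282 and 0.0292 (ranges 0.00152 to 0.274 and 0.00206 to 0.77). Calls of 4 further genes named here ended under alternatives. IL1RN ended without intermediate donor 1 or 3 or non-classical donor 2, 3 or 4 (adjusted p = 0.0513, 0.0741, 0.0524, 0.0576 and 0.0766, range 3.33e-04 to 0.131), and CXCL2 without intermediate donor 3 or non-classical donor 4 (0.0632 and 0.0577, range 0.00108 to 0.0800). TLR2 ended without intermediate donor 2, 3 or 4 or non-classical donor 4 (0.0586, 0.0579, 0.0662 and 0.0554, range 0.00284 to 0.108). These 3 also ended in a fit of only these subsets (0.0907, 0.0800 and 0.0815), and they and CXCL3 without the 2 non-classical arrays highest in NK markers (0.131, 0.0688, 0.0547 and 0.0578, range of CXCL3 0.00201 to 0.0578). Without those 2 arrays IL1RN, CXCL2, TLR2 and CXCL3 differed by 2.28, 1.34, 1.17 and 2.34.

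Lists of NK, T and B cell markers shifted downward in the intermediate against the non-classical arrays, with most members called only for NK cells. Of 9 NK cell markers 8 were called lower, also adjusted over the list alone, with a median of -2.65 (adjusted p = 1.75e-09). The call was lost at adjusted p = 0.122 with an estimated correlation. The adaptor SH2D1B differed by -4.30 (SE 0.53), the cytotoxic protein GNLY by -3.74 (SE 0.70), the interleukin receptor chain IL2RB by -2.91 (SE 0.63) and the protease GZMB by -2.84 (SE 0.62). T cell markers had a median of -0.55 with 1 of 6 called lower, 3 adjusted over the list alone (adjusted p = 0.00282, and adjusted p = 0.274 with an estimated correlation). The called member was the receptor chain CD247 at -2.24 (SE 0.46), and CD3E differed by -0.62 (SE 0.18). The T cell markers CD3G, CD2, IL7R, CD28, BCL11B and TRAT1 were on the array but did not pass the filter on dim genes. The list therefore rests on the 6 members measured. B cell markers had a median of -0.32 with 1 of 8 called lower, and 4 lower and 1 higher adjusted over the list alone (adjusted p = 0.0186, and adjusted p = 0.299 with an estimated correlation). The called member was CD79B at -2.15 (SE 0.34), and BANK1 differed by 0.76 (SE 0.24). Under a repeated quantile normalization CD3E and BANK1 passed as well (adjusted p = 0.0471 and 0.0370, ranges 0.0284 to 0.239 and 0.0370 to 0.196). Proliferation genes had negative differences in 9 of 9 members with a median of -0.35 (adjusted p = 6.37e-04, and 0.0442 with an estimated correlation). Of these the thymidylate synthase TYMS passed, over all genes and adjusted over the list alone, at -1.62 (SE 0.29), while the replication clamp PCNA differed by -0.65 (SE 0.37). The other large decreases in intermediate monocytes were in UICLM (-4.28, SE 0.43), a non-coding RNA, PPP1R17 (-3.12, SE 0.36), the transcription factor ETS1 (-3.06, SE 0.48) and CLC (-4.51, SE 0.99), the Charcot-Leyden crystal protein of eosinophils and basophils. The call of CLC ended without the donor 4 non-classical array (adjusted p = 0.0554, range over its alternatives 4.89e-04 to 0.0752), which was also the array highest in NK markers (10.65). In a fit of only these subsets CLC, CD247, IL2RB and GZMB missed the threshold (adjusted p = 0.0720, 0.0586, 0.0726 and 0.0726). Over the alternatives CD247 ranged from 0.00104 to 0.0586, IL2RB from 9.15e-04 to 0.0726 and GZMB from 9.88e-04 to 0.0726.

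With the donor as a fixed block 1546 genes passed (1203 higher, 343 lower), 924 of the 933 among them, and the block also called CX3CR1 (adjusted p = 0.0456, range 0.0456 to 0.682), FCER1A (-2.61, adjusted p = 0.00489, range 0.00265 to 0.258) and the erythroid markers (-0.31, adjusted p = 0.0525 without and 0.0295 with the block, range 0.00819 to 0.364), of which HBB and SLC4A1 differed by -1.35 (SE 1.28) and -0.35 (SE 0.17). With the 3' minus 5' covariate HLA-DRA passed (0.47, adjusted p = 0.0499, range 0.0499 to 0.515). The count was 602, 578 or 568 without the intermediate array of donor 2, 3 or 4, and 596 without the non-classical array of donor 4. A repeated quantile normalization shifted the differences of genes by a median of -0.11 and centring of each array by a median of -0.14. The split of higher to lower calls became 675 to 433 and 615 to 381. Relative to the quantile shift, classical markers kept a median of 2.66 and non-classical markers -1.69. The B cell call ended there (-0.30, adjusted p = 0.0712, range 0.00581 to 0.299) and without the donor 3 non-classical array (-0.20, adjusted p = 0.105).

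The third comparison, non-classical against classical monocytes, gave the axis on which the intermediate arrays were then placed. FCGR3B was higher in non-classical monocytes, at 10.10 ± 0.65 against 5.53 ± 0.27 (SD, n = 4 each; 4.57, SE 0.28, limma adjusted p = 2.25e-06). CDKN1C was 26.2-fold higher (4.71, SE 0.38, adjusted p = 1.52e-05). CD14 was 39.9-fold lower (-5.32, SE 0.33, adjusted p = 2.56e-06), S100A12 62.1-fold lower (-5.96, SE 0.43) and THBS1 lower to a level under the dim threshold (-6.40, SE 0.43). Other large increases were in UICLM (5.23, SE 0.43), SH2D1B (4.55, SE 0.53), CLC (4.78, SE 0.99), GNLY (3.82, SE 0.70), the actin regulator FMNL2 (3.75, SE 0.24) and the phosphatase PTP4A3 (3.53, SE 0.31). Other large decreases were in RNASE6 (-5.38, SE 0.36), CD163 (-5.12, SE 0.36), QPCT (-4.97, SE 0.41), S1PR3 (-4.91, SE 0.41) and the IgA receptor FCAR (-4.90, SE 0.91). Each moved the same way in 4 of 4 donors, as the rule for naming them required. The call of CLC ended without the 2 non-classical arrays highest in NK markers (4.70, adjusted p = 0.0506, range 2.50e-04 to 0.0506). In all, 1356 genes passed, 418 higher and 938 lower in non-classical monocytes, and 799 differed at least 2-fold (195 higher, 604 lower).

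All 18 classical markers were called lower, also adjusted over the list alone, with a median of -3.00 (adjusted p = 1.72e-27, and 0.0270 with an estimated correlation). VCAN and CCR2 differed by -4.18 (SE 0.26) and -2.99 (SE 0.44). Of 19 non-classical markers 18 were called higher, 19 adjusted over the list alone, with a median of 2.07 (adjusted p = 8.84e-24, and 0.0270 with an estimated correlation). RHOC, CKB and HES4 differed by 3.31 (SE 0.28), 3.22 (SE 0.25) and 3.13 (SE 0.31). CX3CR1 was higher by 1.48 (SE 0.37, adjusted p = 0.0262), a call that ended without classical donor 1, 3 or 4 or non-classical donor 4 (adjusted p = 0.0739, 0.0656, 0.0819 and 0.0709, range 0.00218 to 0.118). HLA-DRA differed by -0.37 (SE 0.18, adjusted p = 0.201). The glucocorticoid list had a median of -1.11 with 13 of 22 lower, 14 adjusted over the list alone (adjusted p = 2.47e-06, and adjusted p = 0.274 with an estimated correlation). Beside THBS1 and CD163, its members CRISPLD2 and FPR1 were lower, at -4.38 (SE 0.39) and -2.65 (SE 0.28). Inflammatory genes had a median of -1.06 with 5 of 21 lower, and 9 lower and 1 higher adjusted over the list alone (adjusted p = 8.16e-04, and adjusted p = 0.496 with an estimated correlation). CXCL3 differed by -3.90 (SE 0.53), CXCL1 by -3.11 (SE 0.73) and CXCL2 by -2.95 (SE 0.51), and all 3 passed. The call of CXCL1 ended without classical donor 3 or 4, non-classical donor 4, or the 2 non-classical arrays highest in NK markers (adjusted p = 0.0579, 0.0613, 0.0579 and 0.104, range 0.00493 to 0.104). The inflammatory list did not pass without the 2 non-classical arrays highest in NK markers (-0.51, adjusted p = 0.187, range 2.32e-06 to 0.496). Complement components did not pass as a list (median 0.26, adjusted p = 0.208), with 4 of 13 higher and 2 lower, and 5 and 4 adjusted over the list alone. C1QA and C1QB were higher by 3.49 (SE 0.23) and 2.93 (SE 0.52). NK cell markers were higher in 9 of 9 members, 8 called, also adjusted over the list alone, with a median of 2.71 (adjusted p = 1.66e-07, and adjusted p = 0.253 with an estimated correlation). T cell markers had a median of 0.45 with 1 of 6 higher, also adjusted over the list alone (adjusted p = 0.0217, and adjusted p = 0.496 with an estimated correlation). CD247 passed at 2.06 (SE 0.46), and the kinase LCK differed by 0.59 (SE 0.25). The same T cell markers as above were left out by the filter on dim genes. The list's call ended under a repeated quantile normalization (0.55, adjusted p = 0.0775, range 0.00306 to 0.496) and without the donor 3 non-classical array (0.32, adjusted p = 0.122). Proliferation genes had a median of 0.36 with 1 of 9 higher, also adjusted over the list alone (adjusted p = 0.00192, and adjusted p = 0.0724 with an estimated correlation). TYMS passed at 1.66 (SE 0.29), and PCNA differed by 0.56 (SE 0.37).

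Another scaling shifted the differences of genes by a median of 0.12 in this comparison, under quantile normalization as under centring. The split of higher to lower calls became 865 to 925 and 709 to 856. Relative to the quantile shift, classical markers kept a median of -2.78 and non-classical markers 2.24. The count of genes was 875, 892 or 800 without the classical array of donor 1, 3 or 4, and 875 without the non-classical array of donor 4. Array weights gave 2223 genes, LCK and PCNA among them.

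**Figure D3:**
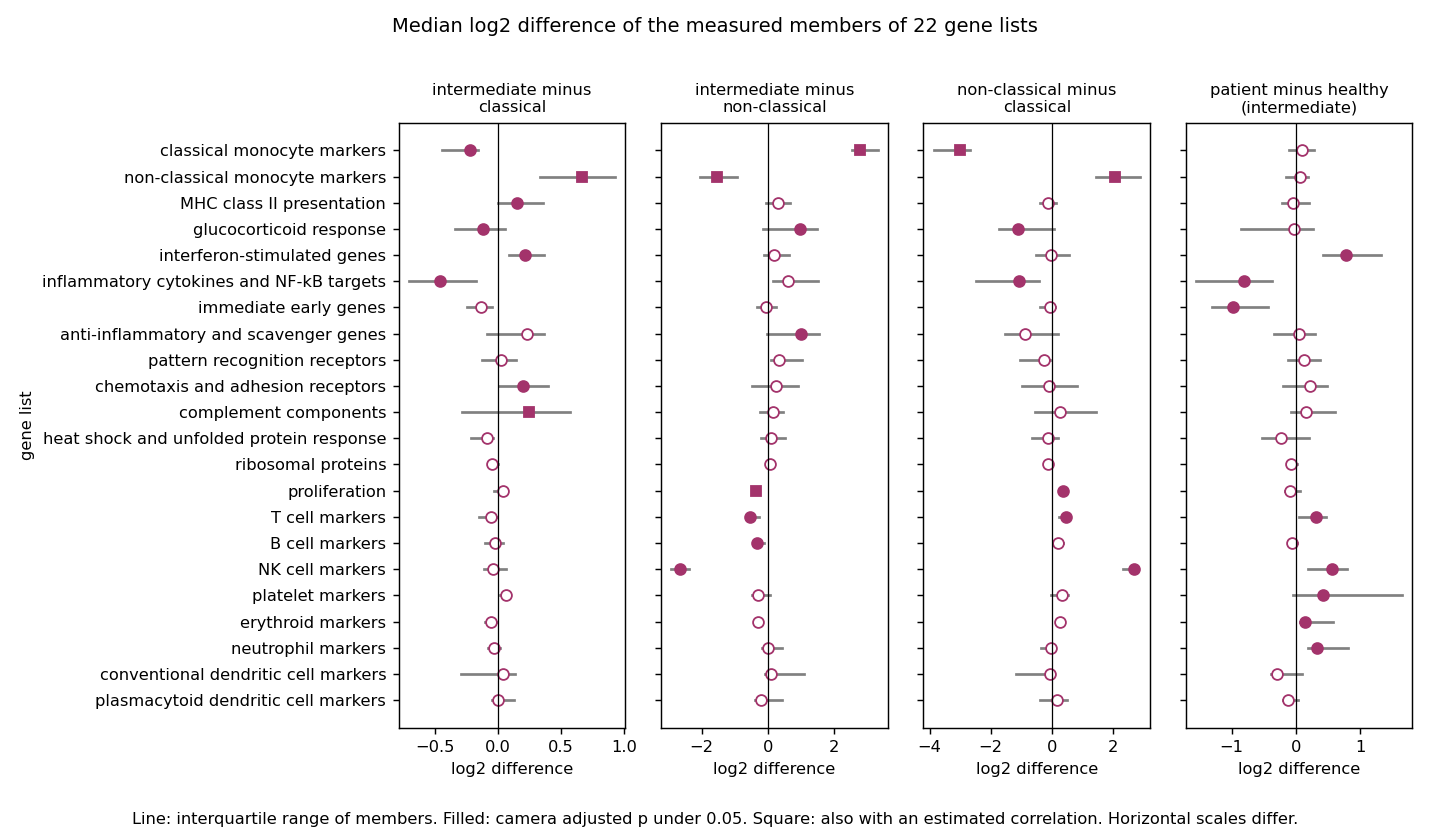
Median log2 difference of each of 22 fixed gene lists (points) with the interquartile range of its members (bars) in 4 comparisons; filled points had a camera adjusted p under 0.05, and squares also with an estimated correlation. Classical markers have medians of -0.22, 2.79, -3.00 and 0.10 from left to right.

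The position of intermediate monocytes on this axis was nearer to classical monocytes. Over the 1356 genes called between non-classical and classical monocytes, the median position was 0.143, where 0 is the classical and 1 the non-classical mean. The intermediate mean lay between the other subsets for 1116 genes (82.3%) and nearer to the classical mean for 1299 (95.8%). Genes higher in non-classical monocytes had a median position of 0.269, and genes lower in them 0.107. Per donor the median position was 0.408, 0.105, 0.0245 and 0.0831 (SD 0.172, n = 4), and it was 0.0513 without donor 1, whose intermediate array had the 3' minus 5' difference of 1.65. Over all probe sets but controls, that array correlated at 0.979 with the donor's non-classical and 0.977 with the classical array. For donors 2, 3 and 4 these values were 0.976, 0.915 and 0.962 against 0.996, 0.995 and 0.989. The cause was not tested. FCGR3B and C1QA were called above classical and below non-classical monocytes. By limma, 0 genes were called above both subsets and 0 below both, with 20 and 4 genes at an unadjusted p under 0.05 in both contrasts. For called genes, unchanged groups simulated 100 times gave a mean of 0 in each direction, and independent lists would give 0.111 above and 0 below both. At the unadjusted p the simulated means were 79.0 above and 77.7 below both, and independent lists would give 25.5 and 2.29. The simulated arrays held no differences between donors, which the fit of the real arrays left in the spread, so the simulated means are not a matched reference for the 20 and 4. With the donor as a fixed block, counted so after seeing the data, 114 genes lay above and 6 below both at the unadjusted p and 0 were called in either direction. Simulations of that fit gave 86.7 and 83.4, and independent lists 89.8 and 5.44. All simulated subsets were alike, whereas 933 genes were called between the real intermediate and non-classical arrays. The simulated means are therefore no matched reference for the 114 and 6 either. HLA-DOA, CD74 and SERPING1 were among the 20. IL6 and FCER1A, a chain of the IgE receptor, were among the 4 (-1.11 and -2.06 against classical, -1.16 and -2.61 against non-classical monocytes).

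The fourth comparison set intermediate monocytes of patients against those of healthy donors. IFIT3, an antiviral protein induced by interferon, was 4.36-fold higher in patients, at 10.29 ± 0.33 (SD, n = 5) against 8.17 ± 0.35 (n = 4), a difference of 2.12 (SE 0.23, limma adjusted p = 0.0334). All 5 patients lay above every healthy donor. It was the only 1 of 12867 genes to pass, while 735 genes (401 higher, 334 lower) had an unadjusted p under 0.05 against 643 expected by chance. Its relatives IFIT2 and IFIT1 differed by 1.78 (SE 0.23, adjusted p = 0.0993) and 1.61 (SE 0.34, adjusted p = 0.294), and IFI44 by 1.37 (SE 0.35), without passing. Interferon-stimulated genes shifted upward as a list, with 23 of 23 members positive and a median of 0.77 (adjusted p = 9.20e-18), a call lost at adjusted p = 0.0592 with an estimated correlation. Of these 1 was called, and 9 were higher adjusted over the list alone. Lists of platelet, neutrophil, NK cell, T cell and erythroid markers shifted upward in the same comparison, and their calls too were lost with an estimated correlation (adjusted p = 0.233, 0.363, 0.540, 0.570 and 0.570). The mean of the list per array differed by exact permutation (two-sided p = 0.0159, adjusted p = 0.116 over 22 lists), where the smallest p the 9 arrays allow is 0.00794.

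Inflammatory genes shifted downward in patients, with 20 of 22 members negative and a median of -0.81 (adjusted p = 8.36e-06), lost at adjusted p = 0.570 with an estimated correlation. CXCL3 and CXCL2 differed by -3.38 (SE 1.07) and -3.02 (SE 1.35). IL1B stood at 11.55 ± 2.78 in patients against 13.90 ± 0.58, a difference of -2.34 (SE 1.19), and CXCL8 and TNF differed by -1.55 (SE 0.98) and -0.78 (SE 0.49). Immediate early genes were negative in 15 of 15 members with a median of -0.97 (adjusted p = 1.98e-04, and adjusted p = 0.660 with an estimated correlation). FOSB, ATF3, NR4A2 and JUN, transcription factors induced within minutes of stimulation, differed by -2.10 (SE 0.93), -1.85 (SE 1.36), -1.69 (SE 0.92) and -1.43 (SE 0.95). These lists moved beside the same higher markers of other blood cells. In these 2 lists 0 genes passed the limma test, over all genes or adjusted over the list alone. Without the 2 most degraded arrays both calls ended, with medians of -0.61 (adjusted p = 0.0711, range 1.70e-12 to 0.669) and -0.68 (adjusted p = 0.280, range 6.78e-08 to 0.937). The immediate early call also ended without patient 1 (-0.64, adjusted p = 0.117) or patient 5 (-0.32, adjusted p = 0.0544) and with the 3' minus 5' covariate (-0.68, adjusted p = 0.0733). The interferon list kept a median of 0.87 without the 2 most degraded arrays (adjusted p = 7.24e-12, range 5.61e-22 to 0.116).

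Markers of other blood cells were higher in the patient arrays as lists. Platelet markers had a median of 0.42 and a mean of 0.93, with 6 of 9 positive and 3 higher adjusted over the list alone (adjusted p = 2.58e-05, and adjusted p = 0.233 with an estimated correlation). The platelet chemokines PPBP and PF4 differed by 3.53 (SE 0.57) and 1.65 (SE 0.33), and the platelet tubulin TUBB1 by 1.67 (SE 0.26). Neutrophil markers had a median of 0.33 (7 of 8 positive, 0 adjusted over the list alone, adjusted p = 0.00180, and adjusted p = 0.363 with an estimated correlation), with the chemokine receptor CXCR2 at 2.72 (SE 0.88) and CMTM2 at 1.55 (SE 0.54). NK cell markers had a median of 0.56 (5 of 6 positive, 1 adjusted over the list alone, adjusted p = 0.00317, and adjusted p = 0.540 with an estimated correlation), with GNLY at 1.49 (SE 0.45) and the lectin receptor KLRB1 at 0.84 (SE 0.31). T cell markers had a median of 0.30 (4 of 6 positive, 0 adjusted over the list alone, adjusted p = 0.0312, and adjusted p = 0.570 with an estimated correlation), with CD3D at 0.64 (SE 0.32) and LCK at 0.48 (SE 0.24). Erythroid markers had a median of 0.13 and a mean of 0.74 (5 of 6 positive, 1 adjusted over the list alone, adjusted p = 0.0414, and adjusted p = 0.570 with an estimated correlation), with the haemoglobin chains HBB at 3.45 (SE 0.93) and HBD at 0.71 (SE 0.27). None of these genes passed over all genes. The T cell and erythroid calls ended without patient 1 (0.28 and -0.03, adjusted p = 0.238 and 0.290, ranges 0.00137 to 0.570 and 0.00271 to 0.570), and both also ended without healthy donor 3 or 4 or without patient 2 or 4 (T cell adjusted p = 0.118, 0.210, 0.0915 and 0.0554, erythroid 0.174, 0.210, 0.0739 and 0.0827). The erythroid call ended too without healthy donor 2 (0.0553) or patient 3 (0.0526) and with no filter on dim genes (0.183). With the 3' minus 5' covariate both calls ended (0.217 and 0.331), and the T cell call without the 2 most degraded arrays (0.186). No list of this comparison held its call with an estimated correlation.

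The genes with the smallest p that did not pass were, in the higher direction, IFIT2, TUBB1, PPBP, the cystatin CST7 (2.27, SE 0.36), GIMAP6 (1.94, SE 0.31), NPTN-IT1 (1.42, SE 0.24) and the interferon-responsive helicase HELZ2 (0.96, SE 0.17). In the lower direction they were the metallothioneins MT1E (-4.00, SE 0.61) and MT1G (-3.02, SE 0.59), EMP1 (-3.42, SE 0.52), the polyamine enzyme ODC1 (-1.59, SE 0.24), ANXA6 (-1.43, SE 0.24), NAP1L5 (-1.52, SE 0.26), APH1A (-1.11, SE 0.20) and NOCT (-1.75, SE 0.34). Their adjusted p ranged upward from 0.0993. Each parted the 5 patients from the 4 healthy donors, which genes picked for a small p tend to do. FKBP5 and TSC22D3, which glucocorticoids induce, differed by 0.34 (SE 0.32) and -0.64 (SE 0.22), CD163 by 0.09 (SE 0.58), CD14 by -0.07 (SE 0.48) and FCGR3B by 1.30 (SE 0.44, adjusted p = 0.691). The glucocorticoid list had a median of -0.03 (adjusted p = 0.145), classical markers 0.10 (adjusted p = 0.576), non-classical markers 0.06 (adjusted p = 0.641) and MHC class II presentation -0.05 (adjusted p = 0.899). Without the 2 most degraded arrays the glucocorticoid list was at -0.53 (adjusted p = 0.00285, range 0.00271 to 0.937).

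The call of IFIT3 depended on single arrays. Without healthy donor 1, 2 or 4 or patient 2, 4 or 5, limma called 0 genes. Adjusted p of IFIT3 was then 0.180, 0.134, 0.0516, 0.0896, 0.0608 and 0.171 (range over its alternatives 0.00360 to 0.317), while its difference stayed between 2.02 and 2.27 without any 1 array. Without healthy donor 3, MT1E passed alone (-4.70) and IFIT3 did not (2.02, adjusted p = 0.0627), without patient 1 NPTN-IT1 and IFIT3 passed, and without patient 3 IFIT3 and IFIT2. Its call also ended under a repeated quantile normalization, an intensity trend with a robust prior and the 3' minus 5' covariate (adjusted p = 0.0643, 0.0657 and 0.0630). Array weights gave 127 genes (85 higher, 42 lower), among them IFIT3, IFIT2, TUBB1, PPBP, HBB, CXCR2, MT1E and FCGR3B. Without the 2 most degraded arrays 0 genes passed (1335 at an unadjusted p under 0.05), with IFIT3 at 2.06 and adjusted p = 0.122.

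**Figure D4:**
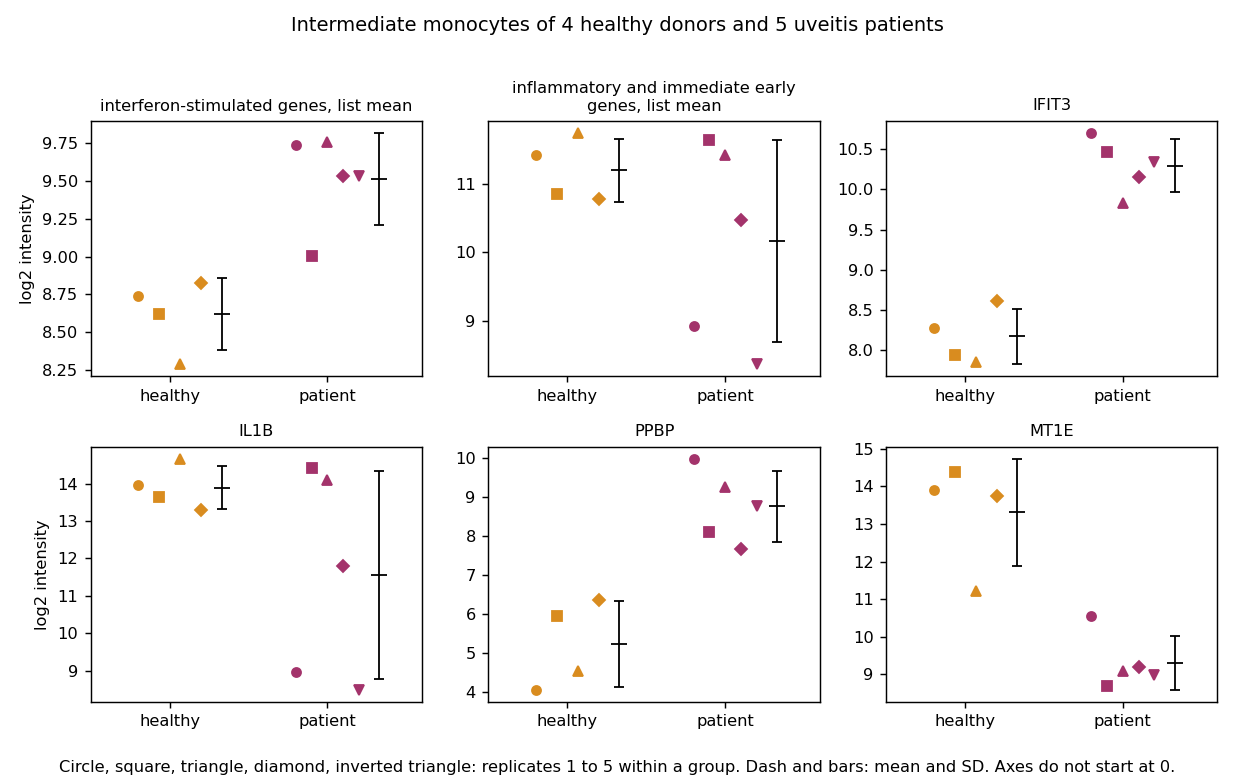
Mean log2 intensity of the interferon list and of the inflammatory and immediate early lists, and log2 intensity of IFIT3, IL1B, PPBP and MT1E, in intermediate monocytes of 4 healthy donors (HD) and 5 patients (P); points are arrays and the marks with bars are the mean and SD. All 5 patient arrays lie above every healthy donor array in the interferon list and in IFIT3.

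The patient difference was also set against the difference between non-classical and classical monocytes, gene by gene. Across 12601 genes Pearson's r was 0.192 (exact permutation over the 126 splits of the 9 arrays, two-sided p = 0.310) and Spearman's rho 0.108 (p = 0.651). Across the 1324 genes called on that axis r was 0.298 (exact permutation p = 0.286) and rho 0.205 (p = 0.468). Genes are not independent replicates, and another split of the 9 arrays reached 0.422 in the first correlation.

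The lists not described above did not pass in any comparison with all arrays. Ribosomal proteins had medians of -0.04 (adjusted p = 0.121) between intermediate and classical monocytes and -0.08 (adjusted p = 0.265) between patients and healthy donors. Heat shock and unfolded protein response genes had -0.09 (adjusted p = 0.272) and -0.23 (adjusted p = 0.576), conventional dendritic cell markers 0.04 (adjusted p = 0.322) and -0.30 (adjusted p = 0.472), and plasmacytoid dendritic cell markers 0.00 (adjusted p = 0.888) and -0.13 (adjusted p = 0.565). Median, mean and test differed in sign for pattern recognition receptors, proliferation, B cell and conventional dendritic cell markers between intermediate and classical monocytes. They also did so for complement and heat shock genes between intermediate and non-classical monocytes, for interferon, immediate early, chemotaxis and heat shock genes between non-classical and classical monocytes, and for anti-inflammatory genes between patients and healthy donors.

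The 4 healthy intermediate arrays were deposited once with each set, and the levels differed between the sets. Of 12601 genes 96 (0.762%) shifted by more than 0.5 on the log2 scale and 2 by more than 1, FCGR3B by 1.46 (SD 0.20 over 4 donors) and ZNF385A by 1.04. Levels of FCGR3B are therefore compared only within a set.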

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

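In 465 groups of 4 or 5 values (quality measures, list means and named genes), 33 had a highest or lowest array whose gap to its neighbour exceeded Dixon's 95% critical share of the range. Chance marks about 1 in 20 groups, or about 23 here. The families of genes chosen after their values were seen were among the genes screened. Of the 33 values, 10 came from the donor 1 intermediate array in the 12-array set, whose 3' minus 5' difference was 1.65, and 5 from patient 1.

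In the donor 1 intermediate array the lowest value stood apart for the mean of the classical markers (10.87, and 11.08 in the second processing), FMNL2 (6.73), HLA-DRA (13.52), QPCT (9.21), FPR1 (11.36), RNASE2 (8.21), MGST1 (8.92) and CCR2 (7.21). The highest value stood apart there for the eosinophil granule protein PRG2 (8.23) and for SERPING1 (7.78). GIMAP6 was lowest in the same array as processed with the patients (6.88). In the donor 3 intermediate array ISG15 (8.94) and RHOC (9.65) stood below the others and NR4A2 (11.90) above them.

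Among classical arrays, donor 1 had the lowest classical marker mean (11.84), QPCT (11.08) and SLC4A1 (6.30) and the highest ITGAL (11.23). Donor 2 had the highest plasmacytoid dendritic cell marker mean (7.62) and the lowest neutrophil marker mean (6.76). Donor 3 had the lowest TYMS (5.17) and the highest ETS1 (6.13). Among non-classical arrays, ALDH1A1 was highest in donor 2 (5.52) and PRG2 in donor 1 (7.19).

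Among patient arrays, patient 1 had the highest 3' minus 5' difference (6.19), the lowest mean correlation with its own group (0.908), and the highest glucocorticoid list mean (10.55), TSC22D3 (13.19) and MT1E (10.55). Patient 3 had the highest IFIT2 (10.80). Patient 5 had the lowest TNF (7.83) and the lowest B cell marker mean (6.26).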

How the results depend on the processing

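The fits without the most degraded arrays, with the 3' minus 5' difference as a covariate, without the arrays highest in NK markers, with the block combined with other choices, the exact test of list means, and named genes under alternatives planned only for counts were chosen after seeing the data, the others before. For named genes 8785 values kept their side of the threshold, 344 lost it and 133 gained it. For lists 1600 kept it, 111 lost it, 68 gained it and 3 turned sign. Between intermediate and classical monocytes limma called 2 genes, and 0 with no filter (277 at an unadjusted p under 0.05), with every probe set tested (382), without the most degraded array (99), with the block and without that array (334) and with the 3' minus 5' covariate (94). It called 1 under repeated quantile normalization, 1 with the donor as a fixed block, 2 with the donor as a random block and 4 with the block and only these subsets in the fit (C1QA, FCGR3B, C1QC and SLAMF7). Leaving out 1 array gave 0 to 2. The glucocorticoid median turned from -0.12 to 0.0581 without the most degraded array (adjusted p = 0.513) and to 0.0637 with the covariate (adjusted p = 0.297, range 7.69e-04 to 0.964), and ran from -0.19 to 0.0581 without 1 array. Of 8 lists called, 2 held with an estimated correlation, 1 by fry and 0 by exact permutation, whose smallest p is 0.0286 before adjustment. With that smallest p an adjusted p under 0.05 required most lists to reach it. The exact permutation therefore could not decide on single lists in any comparison of subsets. Between intermediate and non-classical monocytes 933 genes became 556 at a minimum of 2-fold, 1491 probe sets, 1546 with the donor block, 419 with only these subsets in the fit, 470 with both, and 568 to 1172 without 1 array. Of 8 lists, 3 held with an estimated correlation and 0 by exact permutation, and 13 were called with no filter. Between non-classical and classical monocytes 1356 became 799 at 2-fold, 2519 probe sets, 2223 with array weights and 800 to 1559 without 1 array. Of 7 lists, 2 held with an estimated correlation and 0 by exact permutation. Between patients and healthy donors the 1 gene became 2 probe sets, 127 genes with array weights and 0 under quantile normalization (791 at an unadjusted p under 0.05), with an intensity trend and robust prior (704), with the number as a block although the people differ (792), without the 2 most degraded arrays (1335) and with the covariate (1359). It was 0 to 2 without 1 array. Of 8 lists, 0 held with an estimated correlation, 1 by fry, 0 by exact permutation and 5 with the covariate, and 5 to 9 were called without 1 array. Beyond the changes given beside the comparisons, the fixed donor block in the 3-subset fit ended no other call of a named gene or list, and the other calls it gained were of genes not described for that comparison. The smaller counts at 2-fold and the larger ones by probe set follow from how they were made. For the other changes the cause was not tested. The position of intermediate monocytes (0.143) was 0.143 over genes differing at least 2-fold, 0.140 with no filter and 0.0513 to 0.191 without 1 donor. The correlation of the patient difference with the subset axis was 0.178 with no filter and 0.103 to 0.309 without 1 array. No detection calls were used, so what dim probe sets can show is limited.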

Other observations

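The metallothionein and eosinophil granule genes, the tests of a few patient arrays, of NK cells in the sorted fraction and of 1 array were chosen only after the results were seen. Metallothioneins, small proteins that bind zinc and copper, stood lower in patient intermediate monocytes. The mean of 7 measured members was 10.41 ± 0.79 (SD, n = 5) against 13.25 ± 1.22 (n = 4) log2 intensity, or 7.13-fold lower, and 5 of 5 patients lay below every healthy donor. The family was chosen because MT1E and MT1G were among the genes with the smallest p, so no test of it is given. Differences were -4.00 in MT1E, -2.78 in MT1F, -3.02 in MT1G, -2.82 in MT1H, -2.84 in MT1X and -2.16 in MT2A, and none passed over all genes in the main fit. With array weights MT1E, MT1G, MT1H, MT1X and MT1HL1 (-2.69 there) passed, and without healthy donor 3 MT1E did. The mean difference lay between -2.89 and -2.80 over the alternative settings tried.

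CLC varied between non-classical arrays from 6.27 to 12.75 (9.59 ± 2.73, SD, n = 4). Between non-classical and classical monocytes the eosinophil granule gene PRG2 differed by -0.26 (adjusted p = 0.718). RNASE2 differed by -4.70 (SE 0.56), but stood at 11.41 in classical monocytes and so says nothing on the source of CLC. FCER1A, also a basophil gene, ran from 6.69 to 11.16 over the non-classical arrays. SLAMF7, a receptor of lymphocytes and myeloid cells, was higher in non-classical than in classical monocytes by 2.79.

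Other splits of the arrays were compared with the real ones. Between intermediate and classical monocytes, 2 of 35 splits called at least as many genes as the real 2, so chance was not excluded. The highest other split, with 10 genes, put donors 1 and 3 of both subsets together. Between intermediate and non-classical monocytes 1 of 35 splits, the real one, reached 933. Here the highest other split, with 682 genes, put the donor 1 intermediate array with the non-classical arrays of donors 1, 3 and 4. Between non-classical and classical monocytes 1 of 35 reached 1356 (highest other 0). Both shares are under 0.05 over all splits, but most of these splits put 2 arrays of 1 donor in the same group. Of the 8 splits that part each donor's pair, only the real one called any gene in each of these 3 comparisons (highest other 0). These 8 are too few for a share under 0.05, so with the pairing kept chance was not excluded. Between patients and healthy donors 3 of 100 drawn splits reached the real count of 1 (highest other 4), a share under 0.05 that rests on 1 gene.

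Interferon-stimulated genes were higher in patients as a list (adjusted p = 9.20e-18, and adjusted p = 0.0592 with an estimated correlation, range 5.61e-22 to 0.116). Platelet, neutrophil, NK cell, T cell and erythroid markers shifted upward too, calls lost at adjusted p = 0.233, 0.363, 0.540, 0.570 and 0.570 with an estimated correlation, and for T cell and erythroid markers also without single arrays. Degradation of the 2 most degraded arrays as the whole cause is argued against: without them the median was 0.87 against 0.77, and 22 members stayed higher. The SE of the difference of the list means per array, not of that median, was 0.224. The kept arrays still differed in the 3' minus 5' difference, from -0.005 to 0.63 in healthy donors and from 0.18 to 0.64 in patients. An effect of these smaller differences was not removed by this test and stays open. The exact permutation p of the list mean was 0.0159, with 5 of 5 patients above every healthy donor, but 0.116 after adjustment over 22 lists. The disease, treatment, handling, other blood cells, whose share after the sort on CD14 and CD16 was not measured here, and other differences between the people stay open. No test here sets them apart.

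Inflammatory and immediate early genes were lower in patients as lists (adjusted p = 8.36e-06 and 1.98e-04), calls lost at adjusted p = 0.570 and adjusted p = 0.660 with an estimated correlation (ranges 1.70e-12 to 0.669 and 6.78e-08 to 0.937). Without the 2 most degraded arrays the median of both lists was -0.61 against -0.85. The SE of the difference of the list means per array, not of that median, was 0.813. This is too imprecise to decide, so degradation cannot be told apart from other causes. The list means of 3 of 5 patient arrays lay under every healthy donor (exact permutation p = 0.254), so a few arrays may carry the difference. Immediate early genes also respond to cell handling. Handling, the disease and other blood cells, whose share after the sort on CD14 and CD16 was not measured here, stay open.

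NK cell markers were higher in non-classical than in classical and intermediate arrays. With an estimated correlation these calls were lost at adjusted p = 0.253 and adjusted p = 0.122 (ranges 5.44e-10 to 0.253 and 3.84e-12 to 0.122). By exact permutation of the list mean the adjusted p was 0.0571 in both. That test could not decide: its smallest p is 0.0286 before adjustment, so an adjusted p under 0.05 required most lists to reach it. It also did not keep donors paired. A single array as the cause is argued against: without the array highest in NK cell markers the median difference from classical arrays was 2.03 against 2.71. The SE of the difference of the list means per array, with donors unpaired, was 0.444. Over the 4 arrays the members had a mean pairwise correlation of 0.737, and 9 of 9 were higher. Some NK cells, which can carry CD16, in the sorted fraction could give this. But SH2D1B and GZMB passed the filter on dim genes only through the non-classical arrays, which partly fixed their direction in advance. The NK cell markers KLRD1, GZMA and CD160 were on the array and did not pass that filter. The sort also required CD14, which NK cells largely lack. Expression of the measured NK cell markers by non-classical monocytes themselves stays open, untested.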
